A study of Homo sapiens with 9 samples.

How the data were processed

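The series holds 9 ChIP-seq samples from T47D-MTVL cells, each the only library of its antibody and time. BPTF, HP1γ and LSD1 were profiled at 0 and 30 min of R5020, and histone H2A at 0, 30 and 60 min. The treatment labels gave the hormone dose as 10 nM. Samples were grouped by antibody and time from the sample titles, which gave 9 groups of 1 sample. No replicate check was possible, so no p-value was computed across genes, and no interval below covers the spread between cultures. Wilson intervals cover the sampling of peaks, bootstrap intervals the sampling of genes or peaks, and counting standard errors the sampling of reads. The labels name no input or control library, and none was analysed here.

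Per the submitters' processing notes, Bowtie 1.0.0 and HOMER 4.7.2 were used and the build was hg19, also called GRCh37. The deposited H2A table gives RPKM for protein-coding genes, counted on both strands over version 18 of the GENCODE annotation with HOMER, per the file headers. The HP1γ and LSD1 lists carry a score per peak as deposited by the authors, with 30 as the lowest value. The peak names follow the pattern of the MACS caller, but its version, its control and the definition of the score were not given in the sources used here. Each of these lists came from 1 library. The score was used to rank or filter peaks within a list, except that peaks at progestin response genes were ranked across the HP1γ and LSD1 lists. The displaced and recruited BPTF peaks came as positions without a score, as deposited by the authors, and the caller and the criterion for a change were not given in the sources used here.

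The RPKM of genes with 1 annotated transcript moved in steps of 1 read over the gene's length, and these steps gave the depth of each H2A library. Within a tolerance of 0.02 reads, 96.9% of 130 low values at 0 min, 96.6% of 117 at 30 min and 97.0% of 135 at 60 min came out whole, against 15.2%, 16.5% and 14.6% by chance. The RPKM also followed the number of annotated transcripts across genes (Spearman 0.830), with a median of 0.425 for genes with 1 transcript and 7.10 for genes with 20. The summed values implied 4.26 reads in genes per library read at 0 min, 4.18 at 30 min and 4.23 at 60 min. RPKM levels were therefore compared between times within a gene and not between genes, with some exceptions. Genes were filtered and random lists were matched on mean RPKM, which carries the transcript number. The closing section sets medians of RPKM per annotated transcript over windows of 5 Mb beside peak density. The table listed 20318 genes, of which 17672 had a symbol. A further 2231 took a symbol from version 44 of the GENCODE annotation lifted to GRCh37, to which 96.5% of all genes were matched by identifier. All 13 mitochondrial genes were listed at 0 in every library. The depth of the BPTF, HP1γ and LSD1 libraries was unknown.

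The change of each gene was the log2 ratio of RPKM plus a pseudocount of 0.05, which understates the change of low genes, over 19709 genes with a mean RPKM of at least 0.1. Genes past 0.5 either way were counted, without centring. Counting error was simulated 100 times by drawing reads for unchanged genes at the recovered depths, with the same 0 min draw in both comparisons. For the draws and the counting standard errors, each gene's reads were divided by its number of annotated transcripts. That number came from the later GENCODE annotation named above, not from the version behind the RPKM. Where it is higher than in that version, the standard errors and simulated changes are too large, and where lower, too small. The median change of each of 15 gene lists was placed among 10000 random lists of the same size, matched on mean H2A level in 20 bins. The lists were progestin response, estrogen response, luminal breast markers, basal and mesenchymal markers, immune markers, poly-ADP-ribose and NAD enzymes, chromatin remodellers with LSD1 and HP1, cell cycle G1/S, replication histones, zinc finger genes, olfactory receptors, keratin-associated genes, ribosomal proteins, oxidative phosphorylation and HOX genes. Pattern-based lists were taken from the gene symbols, so a pseudogene such as COX6A1P2 could enter.

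Peaks were compared by an overlap of at least 1 bp, with Wilson 95% intervals over peaks. Chance overlap was the mean over 1000 circular shifts of the peaks within each chromosome. Recruited and displaced BPTF peaks were compared by Fisher's exact test (two-sided) in a family of 4 tests with Benjamini-Hochberg adjustment, which compares peaks of these lists and not cultures. Peaks were assigned to genes over the gene body plus 5 kb on each side. A promoter was the 1 kb on either side of an annotated protein-coding transcription start. Exons, introns and GC content came from the GRCh37 reference. No peak lay past the end of a chromosome.

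The named genes followed a fixed rule. It took the 10 largest rises and 10 largest falls of H2A at 30 min that kept their direction at 60 min outside the families defined by a symbol pattern, and the 2 highest and 2 lowest members of each list. It also took progestin response genes past 0.5, the 5 highest-scored lost and gained peaks of HP1γ and LSD1, the 5 highest-scored kept peaks of each being added after the data were seen, and the 10 highest-scored peaks at progestin response genes. The rule's 5 top BPTF peaks of each list could not be taken, since those lists carry no score. A member of the immune marker list that the rule took is not reported here. Apart from the kept peaks, these rules, the lists, the thresholds and the comparisons were set before the data were examined.

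The alternatives set in advance were pseudocounts of 0.01 and 0.5, no filter or a mean RPKM of 0.3, centring on the median, a threshold of 1, a reciprocal overlap of 50%, widening by 500 bp, equal numbers of top-scored peaks, peaks above the median score, and gene windows of the body alone or 5 kb around the start. Alternatives added after the data were seen took off the median change in 100 bins of gene GC content or kept genes of at least 10 kb. Others matched random lists on GC content, or on GC content in 20 bins and length in 5 bins, moved each peak by 20 to 200 kb in 200 draws, or left out chromosome 3. Promoter shares, with 20 such moves as background, and the counts of list genes with a peak, over 120 pairs of list and peak class, were also added then.

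Intervals of Spearman correlations and GC slopes came from 2000 bootstrap draws over genes. The calculations used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and pysam 0.24.0, samtools 1.23.1, and matplotlib 3.10.9 for plots. The gene-level step was tested on simulated data for 30 against 0 min over 19709 genes, where it called 100% of genes raised 2-fold, 98.9% of genes lowered 2-fold and 0.702% of unchanged genes. The overlap step was tested on simulated positions for 20495 LSD1 peaks with 4099 planted overlaps, where it found 4386, against a mean of 313 after shifting. Depth recovery was tested on simulated H2A values of 285 genes, with a largest error of 0.0444%. RNA levels and binding of the progesterone receptor were not analysed here.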

Results

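Chromatin was profiled by ChIP-seq in T47D-MTVL, a human luminal breast cancer line that carries a reporter driven by the mouse mammary tumour virus promoter. Cells deprived of serum were given R5020, a synthetic progestin, at 10 nM. The 4 antibodies were against histone H2A, a core histone, against BPTF, the largest subunit of the NURF remodelling complex, against HP1γ, a heterochromatin protein encoded by CBX3, and against LSD1, the histone demethylase encoded by KDM1A. H2A was read at 0, 30 and 60 min, and the other proteins at 0 and 30 min, with 1 library for each. The H2A libraries held 141 M reads at 0 min, 169 M at 30 min and 133 M at 60 min, as recovered from the steps in the deposited RPKM. No comparison had a replicate check, and all differences are between libraries. All coordinates are on GRCh37.

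The comparison of H2A at 30 and 0 min asked how core histone occupancy over genes moved soon after hormone. GC-rich genes read lower at 30 min and GC-poor genes read higher. In the GC-poorest decile (26.9% to 37.4% GC, 1971 genes) the median log2 change was 0.23, and in the GC-richest decile (58.1% to 78.3%, 1970 genes) it was -0.33. Chromosome 19, with a median gene GC of 52.9%, had a median change of -0.26, and chromosome 4, at 39.2%, had 0.06. After the GC trend was taken off, both chromosomes lay at 0.00. Across all 19709 genes the median was -0.14 (5th to 95th percentile -0.41 to 0.25), 71.3% of genes read lower, and the change followed GC content (Spearman across genes -0.846, genes not being independent replicates). Past 0.5 on the log2 scale, 68 genes read higher and 392 lower, whereas centring on the median gave 294 higher and 106 lower, so the balance of directions turned with the scaling. With the GC trend taken off, 77 read higher and 47 lower. Counting error alone, simulated on reads divided by transcript number, gave close means of 64.9 and 60.8 (ranges 50 to 78 and 42 to 80).

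**Figure D1:**
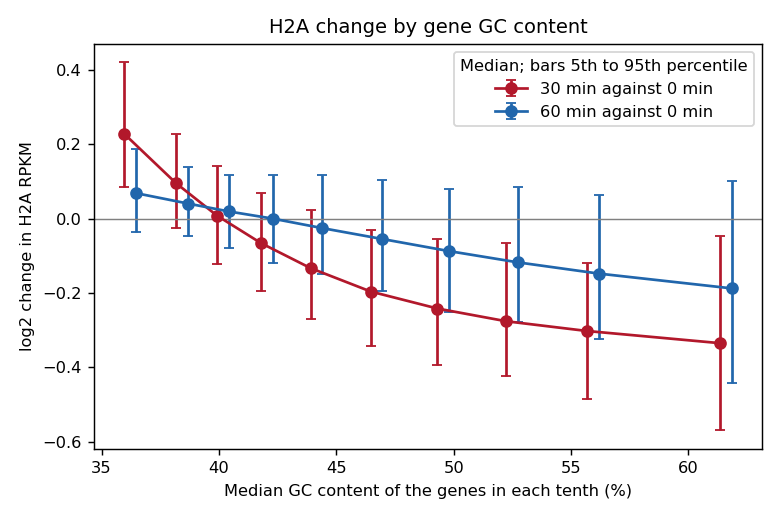
Median log2 change in H2A RPKM (vertical axis) against the median GC content of genes in percent (horizontal axis, points set slightly apart) in 10 groups of genes by GC content, with bars from the 5th to the 95th percentile of genes. At 30 min the medians run from 0.23 to -0.33, and at 60 min from 0.07 to -0.19.

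The genes with the largest changes at 30 min were mostly short and held few reads. Of the 10 with the largest rise, 8 had no symbol and 7 were shorter than 1 kb, and of the 10 with the largest fall the numbers were 5 and 8. The change exceeded 2 counting standard errors in 5 of the rises and 2 of the falls. The largest rise belonged to ENSG00000269506 (chromosome 4, 54927213 to 54927377), with a log2 change of 2.15 on 1 read at 0 min. The X-linked AL353698.1 had 1.38 and CYCSP7, a cytochrome c pseudogene, had 0.84 (counting standard errors 0.56 and 0.65). DUX4L4, a DUX4-like repeat gene on chromosome 4 (191002273 to 191003777), had -1.05 with a counting standard error of 0.22. MRGPRD, a receptor of sensory neurons on chromosome 11 (68747490 to 68748455), had -1.01 with 0.23. RNASE12, of the ribonuclease A family, had -0.98. MMP23B, a metalloproteinase gene, had -0.97, and LSP1P1, a pseudogene, had -0.91. Each of these lay within 2 counting standard errors, computed on reads divided by transcript number. For MMP23B this left 10.9 reads at 0 min, so its standard error depends on that number. DUX4L4 and MMP23B have near-identical copies, so their reads are uncertain.

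Among genes of at least 10 kb, a filter chosen after the values were seen, the 10 largest rises were CSN1S1, CCDC179, IAPP, CLEC7A, SI, POSTN, C18orf54, NOVA1, CDH19 and COL11A1, all between 31.26% and 37.21% GC. The casein gene CSN1S1 (chromosome 4, 70798274 to 70812275) went from 0.914 to 1.47 RPKM, a log2 change of 0.66 with a counting standard error of 0.10. IAPP, which encodes the islet peptide amylin, had 0.58, CLEC7A, a receptor for fungal glucans, had 0.57, and SI, the intestinal sucrase-isomaltase, had 0.56. The matrix protein gene POSTN had 0.55 and the collagen gene COL11A1 had 0.51. The falls were led by TSPO, a protein of the outer mitochondrial membrane, at -0.57 (chromosome 22, 43547937 to 43559216, standard error 0.09) and included the nucleolar protein gene MYBBP1A at -0.54. With the GC trend taken off, CSN1S1 kept 0.29, CLEC7A 0.41, COL11A1 0.14, TSPO -0.25 and MYBBP1A -0.20. At this length 12 genes read higher and 18 lower past 0.5, before the GC trend was taken off. With it taken off, the largest rises that kept their direction at 60 min were SPAG11A at 0.505 (standard error 0.35) and CLEC7A. The largest such fall was NXF3 at -0.33 (standard error 0.11).

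Genes of the progestin response, fixed in advance, did not stand apart at 30 min. Of 32 measured members 28 read lower, with a median of -0.18, at percentile 27.9 of random lists, and relative to the median of all genes it was -0.04. With the GC trend taken off, 17 read lower and 15 higher. MT2A, a metallothionein, had -0.66 (standard error 0.30), and HSD11B2, which inactivates cortisol, had -0.58 (standard error 0.10), the members past 0.5 either way, and with the GC trend taken off they had -0.36 and -0.26, short of 0.5. PDK4, a kinase that restrains pyruvate dehydrogenase, had 0.20 and PGR, the progesterone receptor gene, had 0.11, and with the GC trend taken off these turned to -0.02 and -0.02. The estrogen response list (12 of 16 lower) had -0.18 at percentile 26.8, which turned to 0.01 with 6 lower and 10 higher when the GC trend was taken off, with TSKU, a secreted proteoglycan gene, at -0.37, CTSD, the protease cathepsin D, at -0.35 and NRIP1, a corepressor of nuclear receptors, at 0.16. Luminal markers (15 of 18 lower) had -0.20 at percentile 23.7, which likewise turned to 0.03 with 5 lower and 12 higher, with the keratin KRT19 at -0.36, the ETS factor ELF3 at -0.31, XBP1 of the unfolded protein response at 0.03 and the estrogen receptor ESR1 at 0.02.

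Ribosomal protein genes and HOX genes were lowest as groups. Ribosomal protein genes read lower in 77 of 79 members, with a median of -0.28 (-0.13 relative to all genes), below all 10000 random lists matched on level and below all matched on GC content. With the GC trend taken off, the median was -0.07 and 57 of 79 read lower. RPS15 had -0.71 (standard error 0.22) and RPS28 -0.62 (0.21), while RPS27L had 0.11 and RPL9 0.02. HOX genes, which pattern the body axis, read lower in 38 of 39, with a median of -0.26 (-0.12 relative to all genes, percentile 0.06), but with the GC trend taken off the median turned to 0.01, at percentile 87.1 of lists matched on GC. HOXD4 had -0.81 and HOXD12 -0.78, and HOXD13, at 0.01, was the member that did not read lower. Olfactory receptor genes (271 of 361 lower) had -0.18 at percentile 0.1, and 1.85 when matched on GC, with OR6B2 at -0.98, OR9A2 at -0.95, OR5H14 at 0.59 and OR2M2 at 0.53. With the GC trend taken off, their median was -0.02, with 198 lower and 163 higher. Zinc finger genes (349 of 496 lower) lay high among random lists at -0.09, percentile 99.9, which turned to 0.05 on centring and came to percentile 91.3 when matched on GC. ZNF593 had -0.53, ZNF513 -0.52, ZNF711 0.40 and ZNF214 0.39.

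The remaining lists lay within the middle 95% of random lists matched on level. Replication histone genes (38 of 51 lower, median -0.20, percentile 3.37) ran from HIST1H3H at -0.76 and HIST1H2BL at -0.70 to HIST1H2BI at 0.37 and HIST2H3D at 0.44. Keratin-associated genes of hair (68 of 92 lower, -0.18, percentile 4.34) ran from KRTAP4-16 at -0.78 and KRTAP10-12 at -0.77 to KRTAP2-2 at 0.76 and KRTAP21-1 at 0.83. Both lists lay above all random lists once these were matched on GC, although not on level, and with the GC trend taken off their medians were 0.01 (24 lower, 27 higher) and 0.06 (37 lower, 55 higher). Oxidative phosphorylation genes (55 of 82 lower, -0.09, percentile 94.7, turning to 0.06 on centring) also lay above all lists matched on GC, with a median of 0.03 off the GC trend, and here UQCR11 had -0.58, NDUFS8 -0.48, UQCRQ 0.28 and the pseudogene COX6A1P2 0.78. Immune markers (14 of 16 lower) had -0.19 at percentile 20.99, with the B cell receptor gene CD79A at -0.45, lysozyme LYZ at 0.22 and the leukocyte phosphatase PTPRC at 0.35. With the GC trend taken off, 8 immune markers read lower and 8 higher.

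The other lists had medians above that of all genes, so centring made them positive by construction. Matched on GC, basal and mesenchymal markers came to percentile 30.6 and chromatin remodellers with LSD1 and HP1 to 75.9. Enzymes of poly-ADP-ribose and NAD came to 40.75 and G1/S genes to 97.04, all within the middle 95%. With the GC trend taken off, their medians lay between -0.01 and 0.00. Basal and mesenchymal markers (9 of 16 lower) had -0.05, or 0.10 centred, at percentile 92.8, with the keratin KRT5 at -0.42, the matrix protein SPARC at -0.28, TWIST1 at 0.18 and ZEB1 at 0.33, both transcription factors of mesenchymal cells. Chromatin remodellers with LSD1 and HP1 (18 of 27 lower) had -0.06, or 0.08 centred, at percentile 95.2, with SMARCD2 at -0.39, the BRG1 gene SMARCA4 at -0.38, RCOR3 at 0.28 and the ISWI ATPase gene SMARCA5 at 0.34. Enzymes of poly-ADP-ribose and NAD (15 of 21 lower) had -0.10, or 0.04 centred, at percentile 75.8, with PARP3 at -0.38, MACROD1 at -0.34, TNKS at 0.20 and NAMPT, of NAD salvage, at 0.28. Cell cycle G1/S genes (17 of 20 lower) had -0.10, or 0.04 centred, at percentile 74.8, with the licensing factor CDT1 at -0.42, the helicase subunit MCM7 at -0.39, RRM1 at 0.07 and the cyclin CCNE2 at 0.15.

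**Figure D2:**
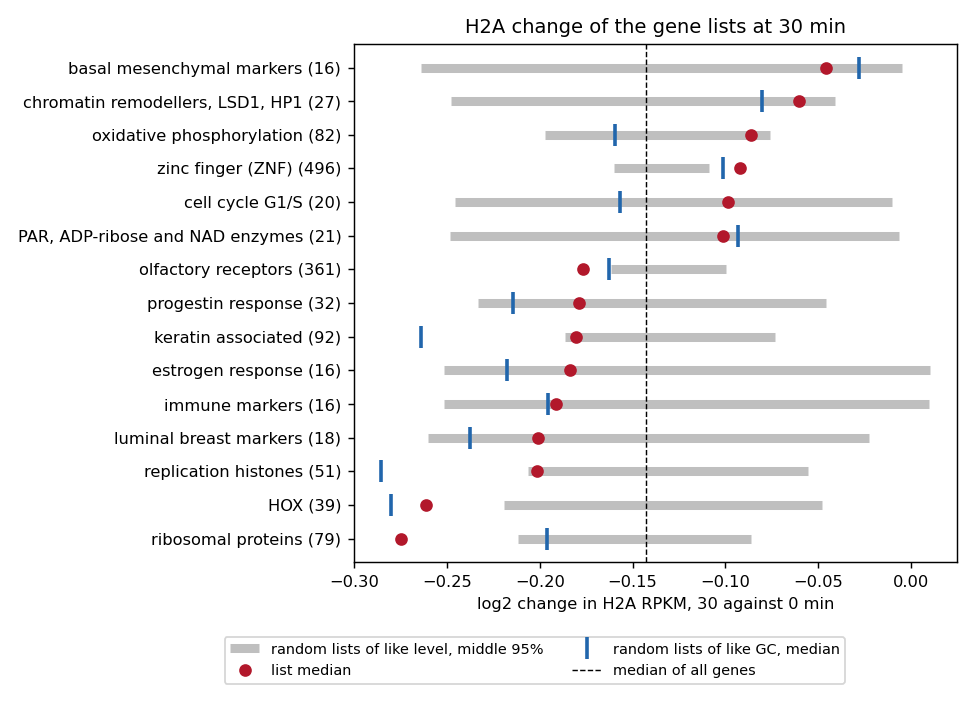
Median log2 change in H2A RPKM at 30 against 0 min (horizontal axis) of the 15 gene lists, with the number of measured genes in brackets, the middle 95% of random lists matched on level as grey bars and the median of random lists matched on GC content as blue ticks. Ribosomal protein genes lie at -0.28 and HOX genes at -0.26, left of their grey bars, and HOX genes turn to 0.01 with the GC trend taken off.

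The comparison of H2A at 60 and 0 min asked whether the change lasted. The GC-dependent change was smaller at 60 min. The GC-poorest decile had a median of 0.07 and the GC-richest had -0.19, with a median of -0.03 over all genes (5th to 95th percentile -0.27 to 0.13) and a Spearman correlation with GC of -0.682 across genes. Past 0.5, 49 genes read higher and 126 lower, or 59 and 96 after centring, while counting error alone gave means of 72.7 and 74.9. With the GC trend taken off, 75 read higher and 57 lower. HOX genes (34 of 39 lower) had -0.12 at percentile 0.07, which came to 72.1 when matched on GC, and immune markers (13 of 16 lower) had -0.12 at percentile 0.61, or 1.15 when matched on GC. Ribosomal protein genes had -0.06 at percentile 3.37, or 31.3 when matched on GC, and the progestin response had -0.05 at 32.0. The other 11 lists had medians between -0.08 and 0.01, within the middle 95% of random lists matched on level. Matched on GC but not on level, replication histone and keratin-associated genes came to percentile 100 and olfactory receptor genes to 99.2, on the opposite side from their 1.85 at 30 min. CLEC7A had 0.50 at 60 min, against 0.57 at 30 min, whereas MT2A went from -0.66 to -0.01. From 30 to 60 min, 149 genes read higher and 58 lower past 0.5, with a median of 0.09. The sign at 30 and 60 min was the same for 80.9% of genes, with a Pearson correlation of 0.679 and a covariance of 0.0199. The shared 0 min library gave 67.2%, 0.513 and 0.00649 by counting error alone, so part of the excess may come from that library.

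HP1γ peaks numbered 31845 at 0 min and 23836 at 30 min, a change of -25.1%. Few positions recurred. Of the 0 min peaks 1372 (4.31%, interval 4.09% to 4.54%) overlapped a 30 min peak, against 366 after circular shifts, 3.75 times as many. The other 30473 were absent from the 30 min list, and 22464 of the 30 min peaks (94.2%, interval 93.9% to 94.5%) were absent from the 0 min list. Among the lost peaks, the highest score was 155.06, in an intron of FNDC3B on chromosome 3 (172004042 to 172005170), followed by an intergenic peak on chromosome 3 (191750864 to 191751993, 142.31). Introns of PEX5L, a regulator of pacemaker channels, and MECOM, a zinc finger oncogene, held lost peaks of 124.51 and 122.95, and a peak on chromosome 8 (69942556 to 69943348) had 126.53. Gained peaks lay between genes on chromosome 10 (46912770 to 46913705, score 132.38) and chromosome 8 (59141178 to 59141810, 111.74). Others lay in introns of RP11-51L5.7 on chromosome 17 (60353777 to 60354375, 116.3) and ATP13A4 on chromosome 3 (193291133 to 193291882, 113.82), and in an intron on chromosome 3 (175008021 to 175008581, 110.45). Of the 0 min peaks also found at 30 min, the highest scores were intergenic, on chromosome 21 (41346259 to 41347211, 141.91) and chromosome 3 (190813697 to 190814757, 132.98). An exon of the mucin gene MUC4 (chromosome 3, 195497635 to 195498396, 117.96) and introns of the potassium channel subunit gene KCNMB3 (111.84) and of LMLN (108.55) followed. When each peak was moved by only 20 to 200 kb, 675 overlaps came by chance, and the ratio was 2.03.

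LSD1 peaks numbered 34990 at 0 min and 20495 at 30 min, a change of -41.4%. Of the 0 min peaks 1299 (3.71%, interval 3.52% to 3.92%) overlapped a 30 min peak, 3.52 times the 369 after circular shifts. The remaining 33691 were lost, and 19187 of the 30 min peaks (93.6%, interval 93.3% to 93.9%) were gained. Lost peaks were led by an intron of ACAP2, a regulator of the GTPase ARF6, on chromosome 3 (195055092 to 195056535, score 152.0), and a further intron there (193147950 to 193148958, 144.3). The next were an intergenic peak on chromosome 5 (67672341 to 67673465, 138.88) and introns of SPATA16, a spermatogenesis gene (138.01), and ATP11B, a phospholipid flippase gene (134.88). Gained peaks were led by an intron of RBPMS, an RNA-binding protein gene on chromosome 8 (30245819 to 30246303, 160.57), and an intergenic peak on chromosome 1 (163521623 to 163522241, 159.73). An intron of TMC6 on chromosome 17 (76111577 to 76112075) had 157.97. KCNS3, a potassium channel gene on chromosome 2, had 138.83, and an intergenic peak on chromosome 21 (10003837 to 10005036) had 125.77. The 5 highest-scored kept peaks lay on chromosome 3, between genes (197795420 to 197796440, 130.51), in an intron of MECOM (169305879 to 169307084, 127.84), between genes (182309643 to 182310821, 120.36), in an intron of the synaptic adhesion gene NLGN1 (119.88) and between genes (196259051 to 196260319, 116.07). Moves of 20 to 200 kb gave 696 overlaps by chance, a ratio of 1.87. At HP1γ peaks of 30 min, a longer list, 1668 of the same 0 min peaks (4.77%) overlapped, 3.68 times circular shifts and 1.93 times such moves. LSD1 peaks of 30 min overlapped LSD1 peaks of 0 min in 6.38% (3.53 and 1.88 times) and HP1γ peaks of 0 min in 4.86% (3.32 and 1.87 times). Relative to chance, LSD1 positions thus recurred about as often as they overlapped the other protein at the other time. The unknown depth of these libraries limits what the peak numbers show.

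Chromosomes differed widely in peaks per Mb for every protein. Chromosome 3 held 4800 HP1γ peaks (24.2 per Mb) and 6079 LSD1 peaks (30.7 per Mb) at 0 min. Chromosome 12 held 22.6 and 27.3 per Mb. Chromosome 2 held 354 HP1γ and 266 LSD1 peaks (1.46 and 1.09 per Mb), and the X chromosome 0.605 and 0.380 per Mb. The fall in peak number at 30 min did not hold on every chromosome. LSD1 peaks were more numerous at 30 min on chromosomes 2 (266 to 530), 4 (292 to 481), 18 (74 to 170), 19 (48 to 143), 20 (232 to 266), 22 (45 to 94) and X (59 to 154), and equal on 16 (473). HP1γ peaks were more numerous on chromosomes 2 (354 to 507), 4 (351 to 424), 18 (107 to 119), 22 (70 to 80) and X (94 to 136). Kept peaks lay on chromosome 3 more often than lost peaks, with 35.7% against 14.1% for HP1γ and 38.6% against 16.6% for LSD1. Displaced BPTF peaks in the authors' deposited table reached 4.33 per Mb on chromosome 3 and 0.378 on chromosome 2.

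**Figure D3:**
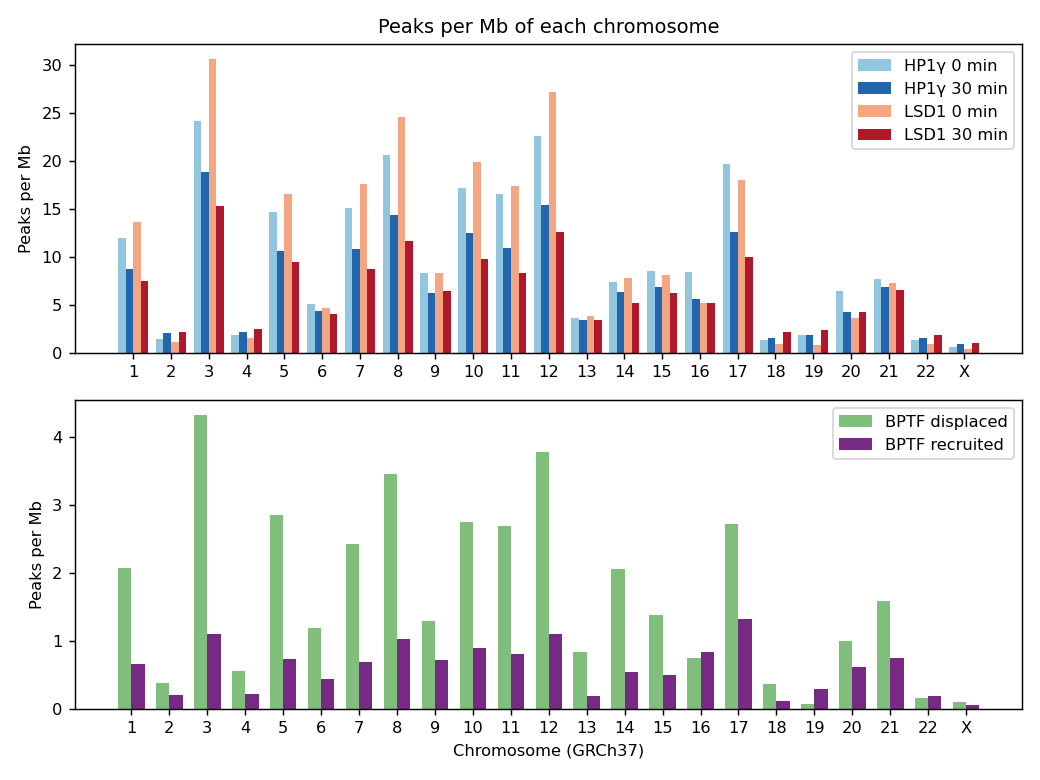
Peaks per Mb (vertical axes, bars from 0) on each chromosome of GRCh37 (horizontal axis), for HP1γ and LSD1 at 0 and 30 min (upper panel) and for displaced and recruited BPTF peaks (lower panel). Chromosome 3 reaches 24.2 per Mb for HP1γ and 30.7 for LSD1 at 0 min, where chromosome 2 has 1.46 and 1.09.

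The comparison of HP1γ with LSD1 asked how often both lay at the same positions. At 0 min 2479 of 34990 LSD1 peaks (7.08%, interval 6.82% to 7.36%) overlapped an HP1γ peak, 3.81 times the 650.4 after circular shifts. At 30 min 730 of 20495 (3.56%, interval 3.32% to 3.82%) did so, 3.49 times the 209 after shifts. The percentage was lower at 30 min, also with equal numbers of top-scored peaks in all lists (6.12% and 3.13%), while the ratios to shifted positions were close. Under moves of 20 to 200 kb these ratios fell to 1.95 and 1.96. Lists of different times gave ratios nearly as high. LSD1 peaks of 0 min at HP1γ peaks of 30 min stood at 3.68 times circular shifts, and LSD1 peaks of 30 min at HP1γ peaks of 0 min at 3.32 times. Moves of 20 to 200 kb put these at 1.93 and 1.87. The excess was thus of like size whether or not the times matched.

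**Figure D4:**
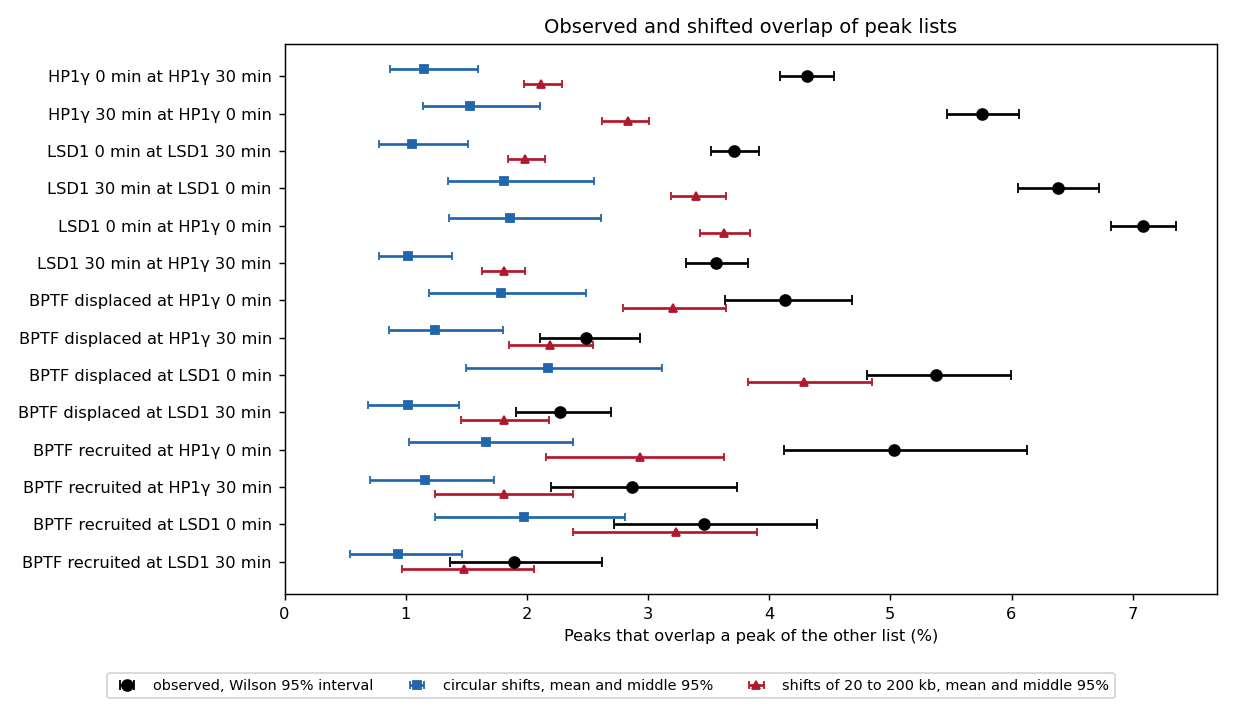
Percentage of peaks of the list named in each line that overlap a peak of the other list (horizontal axis), as black points with Wilson 95% intervals, beside circular shifts (blue) and moves of 20 to 200 kb (red) with means and middle 95% ranges. LSD1 peaks at HP1γ peaks stand at 7.08% at 0 min and 3.56% at 30 min.

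BPTF peaks were compared between positions that lost and positions that gained the remodeller with hormone. The authors' deposited table listed 5546 displaced and 1848 recruited peaks. Displaced peaks coincided with LSD1 peaks of 0 min more often than recruited peaks did, at 298 (5.37%) against 64 (3.46%), with an odds ratio of 0.632 for recruited peaks and p = 0.000759 by Fisher's exact test (adjusted p = 0.00304). With LSD1 and HP1γ peaks above the median score the adjusted p of the exact test was 0.0612, so the call ended there. Positions moved by 20 to 200 kb differed in the same direction, at 4.29% for displaced and 3.23% for recruited peaks, which gave ratios of 1.25 and 1.07. For HP1γ at 0 min the numbers were 229 displaced (4.13%) and 93 recruited (5.03%), with an exact p of 0.1003 (adjusted p = 0.201). For HP1γ at 30 min they were 138 (2.49%) and 53 (2.87%), with an exact p of 0.397 (adjusted p = 0.397), and for LSD1 at 30 min 126 (2.27%) and 35 (1.89%), with an exact p of 0.359 (adjusted p = 0.397). All 8 overlaps exceeded circular shifts, by 1.75 to 3.03 times. Under moves of 20 to 200 kb, displaced peaks at HP1γ of 30 min (ratio 1.14) and recruited peaks at LSD1 of 0 min and 30 min (1.28) no longer stood outside the middle 95% of moved positions. The median GC content was 36.1% for displaced and 44.1% for recruited peaks, and 37.6% for LSD1 and 42.1% for HP1γ peaks of 0 min. Neither the exact tests nor the moved positions were matched on GC content, so these differences were not separated from it.

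Recruited BPTF peaks lay at promoters far more often than displaced peaks, a comparison chosen after the data were seen. In the authors' deposited table, recruited peaks within 1 kb of a protein-coding transcription start numbered 223 (12.1%, interval 10.7% to 13.6%), against 4.59% of moved positions. Of the displaced peaks 161 (2.90%, interval 2.49% to 3.38%) did so, against 2.58%. The odds ratio was 4.59, with p = 1.45e-45 by Fisher's exact test over peaks. HP1γ peaks stood at 4.31% at 0 min and 3.68% at 30 min, above moved positions at 3.18% and 2.94%, while LSD1 peaks stood at 2.66% and 2.90%, close to 2.75% and 2.89%. Recruited peaks had a median GC content of 44.1% and displaced peaks 36.1%. Moved positions were not matched on GC content, so the promoter difference was not separated from this GC difference.

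**Figure D5:**
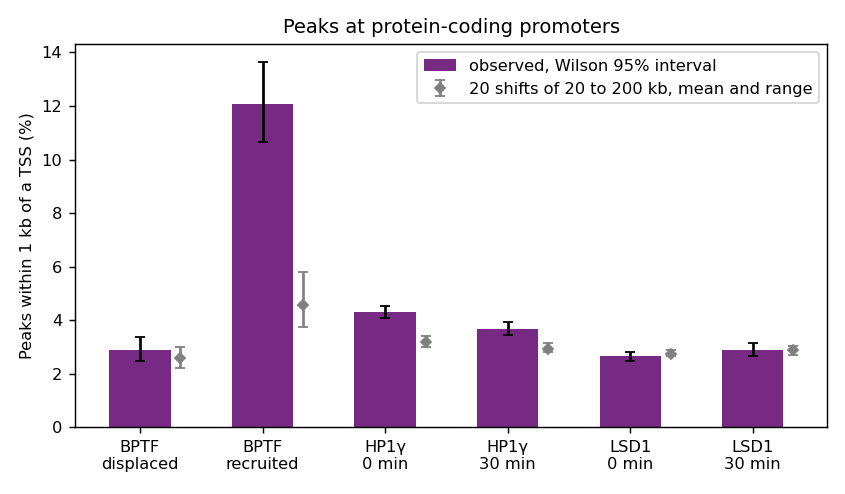
Percentage of peaks within 1 kb of a protein-coding transcription start (vertical axis, bars from 0 with Wilson 95% intervals) for the 6 peak lists, with the mean and range of 20 rounds of moves by 20 to 200 kb as grey marks. Recruited BPTF peaks stand at 12.1% and displaced peaks at 2.90%.

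At genes of the progestin response, recruited BPTF peaks were frequent. Of the 32 genes, 6 held a recruited peak within the gene body or 5 kb of it in the authors' deposited table. They lay in introns of PGR (chromosome 11, 100961265 to 100962002), of ZBTB16, a zinc finger repressor (chromosome 11, 114049889 to 114050486), of the signalling factor STAT5A (chromosome 17, 40446337 to 40446871) and of BCL2L1, which opposes apoptosis (chromosome 20, 30307959 to 30308901). The others were in an exon of the repressor BCL6 (chromosome 3, 187449233 to 187449879) and beside the transcriptional coregulator CITED2 (chromosome 6, 139697777 to 139698264). Random lists matched on gene length held 1.61 such genes on average (middle 95% from 0 to 4), which put the list at percentile 99.8, and at 99.6 when matched on GC content and length. Displaced peaks of the authors' deposited table lay in introns of the growth factor receptor gene EGFR (chromosome 7, 55205087 to 55205680) and of PDK4 (chromosome 7, 95219796 to 95220268), 2 genes against 2.71 in random lists. These percentiles were computed after the data were seen, as part of 120 pairs of gene list and peak class. The random lists were not matched on chromosome.

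HP1γ and LSD1 peaks also lay at progestin response genes, of which 19 of 32 held at least 1 peak of any class. The peaks named here were ranked by score across the HP1γ and LSD1 lists, whose scores may not be comparable. The highest-scored was an LSD1 peak lost beside RGS2, a regulator of G protein signalling (chromosome 1, 192776136 to 192777070, score 67.74). An HP1γ peak near BCL6 was kept (chromosome 3, 187465842 to 187466452, 63.46), and another in an intron was lost (187444949 to 187445664, 47.56). LSD1 peaks were lost beside the Krüppel-like factor KLF4 (chromosome 9, 110244294 to 110245000, 60.79), in introns of EGFR (chromosome 7, 55141498 to 55142383, 48.21, and 55160378 to 55161143, 45.49) and at the promoter of NDRG1 (chromosome 8, 134306162 to 134306768, 46.65). LSD1 peaks were gained beside PGR (chromosome 11, 100897657 to 100898255, 55.45) and in an intron of FKBP5, a chaperone of steroid receptors (chromosome 6, 35570567 to 35571078, 47.52). EGFR also gained an HP1γ peak (chromosome 7, 55162848 to 55163213, 45.74). In all, PGR lost 3 LSD1 peaks and gained 1, FKBP5 lost 2 and gained 3, and EGFR lost 9 and gained 4, while EGFR lost 7 HP1γ peaks and gained 2. The lost LSD1 peaks scored 32.24 to 33.6 at PGR, 30.95 and 34.65 at FKBP5, and 33.65 to 48.21 at EGFR. The lowest score in the list was 30. Of all LSD1 peaks of 0 min only 3.71% overlapped a 30 min peak, so absence at 30 min was the usual case. Lost LSD1 peaks touched 10 of the 32 genes, against 7.94 in random lists (percentile 81.6), and gained LSD1 peaks 9, against 7.13 (81.0). Lost HP1γ peaks touched 8, against 9.05 (33.8), and gained HP1γ peaks 4, against 7.54 (5.06), all within the middle 95% of random lists.

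Genes near peaks were compared in H2A to ask whether histone occupancy moved where BPTF, HP1γ or LSD1 did. Genes with displaced BPTF peaks (1856 genes) had a median H2A change of 0.03 at 30 min and genes with recruited peaks (1067 genes) -0.11, against -0.16 in random lists matched on level for both. HP1γ lost, kept and gained peaks gave -0.08, -0.03 and -0.05, and LSD1 peaks gave -0.02, 0.04 and -0.04, all of these at percentile 100. The genes of the 8 classes had median GC contents from 39.4% to 43.5%. Matched on GC content and length, every class came within the middle 95% of random lists, with displaced BPTF at percentile 39.3 and recruited at 10.45. Among random lists matched on level alone, genes with a recruited peak within 5 kb of their start lay at percentile 1 instead of 100, a reversal of direction. That window was not run with lists matched on GC content.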

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

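Centring, the pseudocount, the threshold and the score filters were planned, while the tests on GC content, gene length, moves of 20 to 200 kb and chromosome 3 were chosen after the results were seen. Of the values that answer a comparison, 38 under alternatives set in advance stayed within their bounds, 54 moved, 3 passed a threshold they had missed (before adjustment) and 1 reversed. Under added alternatives 22 stayed, 18 moved, 1 passed a threshold and 5 no longer passed. For the gene lists, 115 of 120 placements under alternatives set in advance stayed on the same side of the middle 95% and 5 came to lie outside, while matching on GC kept 21 of 30, put 6 outside and brought 3 inside. No paired analysis was possible because each group holds 1 library. Unknown depth of the BPTF, HP1γ and LSD1 libraries limits every peak number, and reads per gene limit H2A changes of short genes.

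H2A counts past the threshold were sensitive to low values. A pseudocount of 0.5 left 7 genes higher and 54 lower at 30 min and 3 and 4 at 60 min, because it shrinks the change of low genes, and 4 lists stood outside at 60 min instead of 2. A mean RPKM of at least 0.3 left 30 higher at 60 min. A threshold of 1 left 6 higher and 5 lower at 30 min and 5 and 5 at 60 min. Centring gave 294 higher and 106 lower at 30 min. With the GC trend taken off, 47 were lower at 30 min, and 75 were higher and 57 lower at 60 min. Genes of 10 kb or longer, a smaller set, gave 12 higher and 18 lower at 30 min and 1 and 2 at 60 min. With lists matched on GC, 4 stood outside at 60 min.

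Peak sharing changed with the definition of overlap and the peaks taken, and below the order is HP1γ peaks of 0 min found at 30 min, HP1γ of 30 min found at 0 min, and the same for LSD1. A reciprocal overlap of 50% gave 2.24%, 2.99%, 1.67% and 2.85%. Widening by 500 bp gave 8.51%, 11.2%, 7.69% and 12.6%. Equal numbers of top-scored peaks gave 4.77%, 4.80%, 4.59% and 4.64%. Peaks above the median score gave 3.13%, 4.22%, 2.89% and 4.96%. Leaving out chromosome 3 gave 3.26%, 4.38%, 2.76% and 4.58%. LSD1 peaks at HP1γ peaks at 0 and 30 min were 3.94% and 1.80% with reciprocal overlap, 6.12% and 3.13% with equal numbers, 5.47% and 2.61% above the median score, and 5.48% and 2.72% without chromosome 3. A stricter overlap lowers such shares and widening raises them by construction. Equal numbers of top-scored peaks raised the shares of 0 min peaks found at 30 min and lowered those of 30 min peaks found at 0 min. Lists of equal length give nearly the same share both ways, since both count the same overlaps. Leaving out chromosome 3 lowered the shares because kept peaks lay there more often than lost peaks, with 35.7% against 14.1% for HP1γ and 38.6% against 16.6% for LSD1. Above the median score each list held fewer peaks to overlap. Other causes, and those of the lower share of LSD1 peaks at HP1γ peaks, were not tested.

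BPTF shares at HP1γ and LSD1 peaks moved too. BPTF peaks widened by 500 bp gave, for displaced and recruited peaks, 6.56% and 8.17% at HP1γ of 0 min, 4.54% and 4.65% at HP1γ of 30 min, 9.23% and 5.95% at LSD1 of 0 min, and 4.24% and 3.08% at LSD1 of 30 min. Above the median score these were 2.22% and 3.14%, 1.53% and 0.974%, 3.16% and 2.16%, and 1.28% and 1.30%. Equal numbers of top-scored peaks gave 2.72% and 3.57% at HP1γ of 0 min and 3.64% and 2.33% at LSD1 of 0 min. Without chromosome 3 displaced peaks stood at 3.43%, 1.86%, 4.18% and 1.56% in the same order. Fisher's exact test at HP1γ of 0 min gave unadjusted p = 0.0202 with widened peaks, 0.0297 above the median score and 0.0232 without chromosome 3, and at LSD1 of 30 min 0.0273 with widened peaks, or adjusted p = 0.0364, 0.0612, 0.0463 and 0.0364 in that order. At LSD1 of 0 min the unadjusted p of the exact test ranged from 6.45e-06 to 0.0306 over the alternatives run and the adjusted p from 2.58e-05 to 0.0612, the latter above the median score. Moves of 20 to 200 kb lowered the ratio to chance to 1.14 for displaced peaks at HP1γ of 30 min, and to 1.07 and 1.28 for recruited peaks at LSD1 of 0 and 30 min. For H2A of genes with recruited peaks at 30 min, the window of 5 kb around the start gave percentile 1 among lists matched on level, reversed from 100. Matching on GC content and length, run only for the gene body plus 5 kb, gave 10.45 for recruited and 39.3 for displaced peaks. The cause of the reversal was not tested.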

Other observations

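Other gene families also differed in peaks within the gene body or 5 kb of it, in counts computed after the data were seen. HOX genes held recruited BPTF peaks of the authors' deposited table in 8 of 39 members, from 3 distinct peaks in the clustered genes, against 1.03 in random lists matched on length. HP1γ peaks were gained at 14 HOX genes, against 4.703, from 8 distinct peaks, and lost at 11, against 6.79 (percentile 95.6, within the middle 95%), and LSD1 peaks were lost at 10, against 5.26 (percentile 98.2). Replication histone genes, which lie in clusters, held lost LSD1 peaks at 21 of 51 members (12 distinct peaks), against 6.001, lost HP1γ peaks at 19 (16 distinct), against 6.69, gained HP1γ peaks at 16 (8 distinct), against 5.04, and recruited BPTF peaks of the authors' deposited table at 6 (3 distinct), against 0.688. Keratin-associated genes held kept HP1γ peaks at 7 of 92 members (3 distinct), against 0.885, gained HP1γ peaks at 15, against 8.75, lost HP1γ peaks at 18, against 11.3, lost LSD1 peaks at 17, against 10.6, and displaced BPTF peaks of the authors' deposited table at 4, against 1.35, of which the lost HP1γ and the displaced BPTF counts fell within the middle 95% when matched on GC content and length (percentiles 96.7 and 97.0). Clustered genes share peaks, so these gene counts are not independent.

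Zinc finger genes held fewer peaks of several classes. Of 496 members, 9 held recruited BPTF peaks of the authors' deposited table, against 20.9 in random lists matched on length (percentile 0.11), 23 held displaced ones, against 32.9 (2.45), 88 held lost LSD1 peaks, against 115 (0.135), and 75 held gained LSD1 peaks, against 98.6 (0.21), whereas 15 held kept HP1γ peaks, against 8.79 (97.6, or 95.2 when matched on GC content and length). Olfactory receptor genes held no recruited BPTF peak in 361 members, against 4.68 (0.185), and lost HP1γ peaks at 34, against 46.8 (0.605). Enzymes of poly-ADP-ribose and NAD held recruited BPTF peaks of the authors' deposited table in 4 of 21, against 1.60 (percentile 96.1, within the middle 95%). Random lists were not matched on chromosome, here or for the families above, and chromosomes differed widely in peak density. Recruited BPTF peaks, for instance, stood at 0.288 per Mb on chromosome 19 and 1.11 on chromosome 3. These counts do not separate a trait of a family from the chromosomes on which its genes lie.

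The tests of sequencing depth, of transcript-wise counting, of copy number and of the 30 min libraries below were chosen only after the results were seen. The first pattern is the fall of H2A in GC-rich genes and the rise in GC-poor genes at 30 min. Sequencing depth as the only cause is argued against, since the 60 min library was shallower and the 30 min library deeper than 0 min, yet the 60 min change kept the sign of its correlation with GC at -0.682. Both changes share the 0 min library, however. The change from 30 to 60 min, which does not use it, had a Spearman correlation with GC of 0.652, the direction that depth would give. A part played by depth stays open. Transcript-wise counting acts on a gene alike at each time, so it largely cancels in the change, and its test could hardly have come out otherwise. Among the 2463 genes with 1 annotated transcript, where each read counts once, the Spearman correlation with GC was -0.614 (interval -0.643 to -0.584). The trend was thus present there too. A GC bias of the libraries cannot be told apart from a change in H2A, since the slope in olfactory receptor and keratin-associated genes, tissue-specific families, was 0.413 of that over all genes, with an interval (-0.0125 to -0.00392 log2 per GC point, against -0.0201) that spans the bound set in advance. A change of H2A over GC-rich chromatin with hormone stays open as a hypothesis, on which the percentile of 92.4 of the progestin response among lists matched on GC decides nothing, since 32 genes could not make a trend over 19709 and a percentile within the range excludes no effect, so the bound set in advance was wrong.

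The second pattern is the crowding of HP1γ and LSD1 peaks on a few chromosomes and the low sharing between 0 and 30 min. Crowding is consistent with DNA copy number of the cell line, since over 559 windows of 5 Mb peak density followed H2A per transcript at 0 min (Spearman 0.744 for LSD1 and 0.841 for HP1γ), which would not by itself account for low sharing. The H2A level was 0.437 on chromosome 3 and 0.268 on chromosome 2, a ratio of 1.63 (window medians), against ratios of 8.29 for HP1γ and 13.3 for LSD1 peaks, so a proportional effect of copy number falls short of the crowding and its size stays open. Calls near the threshold may account for part of the low sharing, since the kept share was 3.03 times as high in the top score decile as in the lowest for LSD1 (interval 2.40 to 3.86) and 3.61 times for HP1γ (2.86 to 4.7), although the ratio was 1.81 for the 30 min peaks of either protein and even the top deciles of 0 min kept only 7.55% and 8.95%. The kept shares by decile were not set against moved positions, so chance overlap where peaks crowd was not separated from them. Movement of both proteins with hormone was not tested apart from calls near the threshold, as only 1 library per time was analysed here.

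The third pattern is the lower GC content of displaced than of recruited BPTF peaks in the authors' deposited table, by 7.96 percentage points. The promoter preference of recruited peaks does not account for it, since the difference beyond 5 kb of a transcription start was 7.16 points (interval 6.68 to 7.61). A shift of all 30 min libraries to GC-rich DNA is argued against, since HP1γ peaks at 30 min changed in median GC by -3.12 points (interval -3.27 to -3.00), although LSD1 peaks moved by 0.553 points the other way. A GC difference between the BPTF libraries alone was not tested and stays open, as does recruitment to GC-richer chromatin.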
